A study of Mus musculus with 24 samples.

How the data were processed

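Liver RNA of 24 C57BL/6JRcc mice, all labelled female, was measured on Agilent 2-colour arrays, 1 array per mouse. The mice were weaned at 3 weeks of age onto one of 2 semi-synthetic diets that differed in their monosaccharide, and the right liver lobe was taken at postnatal day 42. The monosaccharide was glucose alone (GLU, 12 mice) or glucose and galactose in equal parts (GLU+GAL, 12 mice). Per the labels' protocols, the RNA of each mouse was labelled with Cy5 and with Cy3, all Cy3 material was pooled, and each Cy5 sample was hybridised against that pool. The dyes were not swapped, so a dye effect common to all arrays cancels in the difference between diets.

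The deposited scanner files held spot intensity values in both channels, extracted with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. Per the file headers, the mean signal and the median local background were intensities as scanned, and the processed signals were intensities after Feature Extraction's own background and dye correction. The log10 ratio of Cy5 over Cy3 that the scanner files also hold was deposited by the authors and was not used in any comparison here. A table of the whole series, deposited by the authors, held log2 values for 29287 spots. Each of its 24 columns matched the Cy5 channel of its own array best once genes were centred, with correlations to the log2 Cy5 signal from 0.993 to 0.999. All 24 columns had a median of 8.6, and genes were not centred. How these values were scaled and how the spots were selected is not given in the sources used here. No 2 arrays held identical values.

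Each array carried 62976 features, of which 59305 were not controls and represented 56605 probes. Mean signals were corrected with the local background by normexp with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalised within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with data.table (version 1.17.8). Spots flagged as outliers were left out, as were controls after normalisation, and spots of a probe were averaged. A probe was used when its Cy5 signal was well above background on at least 6 arrays of at least 1 diet, which 26675 probes were. A gene was represented by its probe with the highest mean intensity over all arrays, which gave 18650 genes. Probe accessions were looked up in a RefSeq gene table. Of all probes, 32994 were named by accession, 10224 by a current symbol and 523 by an older symbol, and 12864 kept only the name in the scanner file. Of the tested genes, 14644 had a matched symbol. No genome was used, so positions are not given.

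Diets were compared as GLU+GAL minus GLU with limma's lmFit and eBayes over all 24 arrays, 2-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05 on the adjusted p. Gene lists for 45 pathways, cell types and neighbouring tissues were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated for each list, and with fry, which tests whether the genes of a list move one way on balance. For each mouse the mean log2 ratio over the members of a list was taken, and the diets were compared by a 2-sided permutation test with 100000 resamples. The groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. With fewer than 10 genes past the adjusted threshold, the rule named the 10 largest differences in each direction at an unadjusted p under 0.01, among genes with a symbol and the same direction of difference within each of the 3 slides. Without that condition on slides it also named measured genes of the galactose pathway and, for each list past the camera threshold, the 4 members with the smallest p. One gene that the rule named is not reported here. Plots were drawn with matplotlib 3.10.9.

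The steps were tested on simulated data with the means and spreads of the 18650 genes, 12 mice per diet and 200 genes changed. Of 50 genes changed by a log2 difference of 0.3, 64% were recovered, and of 50 changed by 0.6, 96%. Of 50 each changed by 1.0 and 1.5, 100% and 98% were recovered. There were 12 false calls among 191. Many large changes make the adjustment more lenient, so these shares do not hold for a lone change. In the real data Hspb1, at a difference of -0.60, had an adjusted p of 0.672 in limma. In a second simulation all 3 lists shifted by 0.2 were called by camera, fry and the permutation test. Among lists that shared no gene with these, camera called 1. The simulated genes were independent of each other, which members of a list in liver are not.

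The slide served as the batch. Each of the 3 slides held 8 arrays, 4 per diet, and was scanned once, so scan and slide cannot be told apart. Alternatives covered background correction, normalisation, the use of Cy5 alone, the deposited value table, the filter, the probe rule, slide and replicate number as blocks, each slide alone, array weights, other settings of the tests and leaving out each array in turn. The precision is limited by the number of arrays.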

Results

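The study asked how replacing part of the glucose in the diet after weaning with galactose, the other monosaccharide of milk sugar, affects the liver of young mice. The mice, labelled female and of the inbred laboratory strain C57BL/6JRcc, drew 32% of their dietary energy from monosaccharides. For 12 mice this was all glucose (GLU), and for 12 others galactose took the place of part of it, to equal shares (GLU+GAL). Energy from fat was 16%, from protein 20% and from starch 32% in both diets. The mice ate these diets from 3 to 6 weeks of age and were killed without food in the light phase, and messenger RNA of the right liver lobe was measured on 24 arrays as the log2 ratio of each mouse over a pool of all mice. Between 46.6% and 51.3% of spots per array were well above background in the Cy5 channel, which carried the individual mouse, and between 36.5% and 47.8% in the Cy3 channel of the pool. One array, GLU+GAL 4, stood apart in the pool channel, with a median Cy3 correlation with the other arrays of 0.9681, the next lowest being 0.9897, and its log ratios had an SD of 0.44, the next highest being 0.33. On another array, GLU+GAL 12, the Y-linked Eif2s3y and Ddx3y were well above background and Xist, transcribed from the inactive X chromosome, was not, although all mice were labelled female. The Y-linked Uty was not well above background on any array.

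Among genes named at an unadjusted p under 0.01, the largest higher value in GLU+GAL livers was that of Sult1e1, an oestrogen sulfotransferase, at a log2 difference of 1.17 ± 0.40 (SE, n = 12 per diet), a 2.24-fold higher mean. The largest lower values at that level were those of Igtp, an interferon-inducible GTPase, at -0.62 ± 0.18, of Hspb1, a small heat shock protein, at -0.60 ± 0.13, and of Saa3, an inducible serum amyloid A, at -0.54 ± 0.14. None of the 18650 genes passed the adjusted threshold in limma, where the lowest adjusted p was 0.672. At an unadjusted p under 0.05 there were 801 genes (307 higher and 494 lower in GLU+GAL), against 932.5 expected by chance. The other limma fits, with a trend and robust variances or with array weights, also gave 0 genes.

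The genes with the largest differences at an unadjusted p under 0.01, all of which missed the adjusted threshold, were named in both directions. On the higher side, Sult1e1 was followed by Hnf4aos (0.60 ± 0.19, SE), an antisense transcript at the gene for the hepatocyte factor Hnf4a, Gm10804 (0.55 ± 0.19), Slc15a2 (0.55 ± 0.16), a peptide transporter, and Cpe (0.32 ± 0.11), carboxypeptidase E. Iqcg (0.30 ± 0.09), Zfp787 (0.29 ± 0.06), Ackr3 (0.26 ± 0.08), Ube4a (0.26 ± 0.07) and 2810408I11Rik (0.25 ± 0.07) differed less. Zfp787, Ackr3, Iqcg and Ube4a were each above the GLU mean in 12 of 12 GLU+GAL mice. Sizes on this side varied: Sult1e1 differed by 1.19, 0.22 and 2.09 within slides 1, 2 and 3, and with Agilent's processed signals Slc15a2 differed by 1.33, Gm10804 by 1.19, Ackr3 by 0.63 and Cpe by 0.60. Other probes gave as little as 0.02 for Zfp787 and 0.03 for Ube4a. Without array GLU 3, Zfp787 passed the threshold with limma's adjusted p of 0.030. On the lower side, besides Hspb1 and the serum amyloids Saa3 and Saa2 (-0.39 ± 0.13), stood 6 interferon-inducible GTPases, Igtp, Ifi47 (-0.47 ± 0.16), Irgm2 (-0.42 ± 0.13), Gbp7 (-0.42 ± 0.14), Iigp1 (-0.41 ± 0.12) and Gm4951 (-0.36 ± 0.10), and the interferon-induced chemokine Cxcl10 (-0.43 ± 0.14). Igtp, Hspb1, Iigp1 and Gm4951 were below the GLU mean in 12 of 12 GLU+GAL mice. Like those for the higher genes, these counts follow in part from how the genes were chosen and are no separate support. The choice asked for a small p and the same direction within each slide. Sizes varied among the lower genes too. Within slides 1, 2 and 3 Igtp differed by -0.22, -1.10 and -0.53 and Gbp7 by -0.14, -0.71 and -0.40. Cxcl10 was steadier, at -0.39, -0.45 and -0.44. Without array GLU 11 the difference of Igtp was -0.46.

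Genes of the acute phase, a response of the liver to inflammation, were lower in GLU+GAL livers as a group. The list held mainly genes for plasma proteins, with some for membrane and intracellular proteins. Of 32 measured members 28 had a lower mean, 14 of them at an unadjusted p under 0.05 and none higher at that level. No member passed the threshold over all genes, and 9 were lower when adjusted over the list alone. These included the fibrinogen chains Fgb (-0.26 ± 0.06, SE) and Fga (-0.28 ± 0.08), the serum amyloids Saa1, Saa2 and Saa3, the metalloreductase Steap4 (-0.22 ± 0.05), the haem carrier Hpx (-0.24 ± 0.08) and the copper carrier Cp (-0.26 ± 0.08). In Cy5 alone Fgb differed by -0.09. In the log2 ratios of Cy5 over Cy3 the second probe of Fga differed by -0.05. Not all members moved this way, with Orm1 at -0.01 ± 0.08, Lcn2 at 0.12 ± 0.15 and Orm3 at 0.16 ± 0.13. The list mean per mouse was 0.19 ± 0.13 (SD, n = 12) on GLU and 0.04 ± 0.13 on GLU+GAL, a difference of -0.15, and 12 of 12 GLU+GAL mice lay below the GLU mean. The list fell by camera (adjusted p = 2.35e-12), and it was the only one of 45 lists to hold with an estimated correlation (adjusted p = 0.0135) and with fry (adjusted p = 0.0178). The permutation test of the per-mouse means gave p = 0.0105 and an adjusted p of 0.393. With slide as a block the difference was -0.15, which was fixed by the design, as each slide held equal numbers of both diets. In the authors' value table it was -0.09. It was -0.17 and -0.27 within slides 1 and 2 and 0.0019 within slide 3. There camera still placed the list lower (adjusted p = 0.0381), so that mean and test differed in sign.

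**Figure D1:**
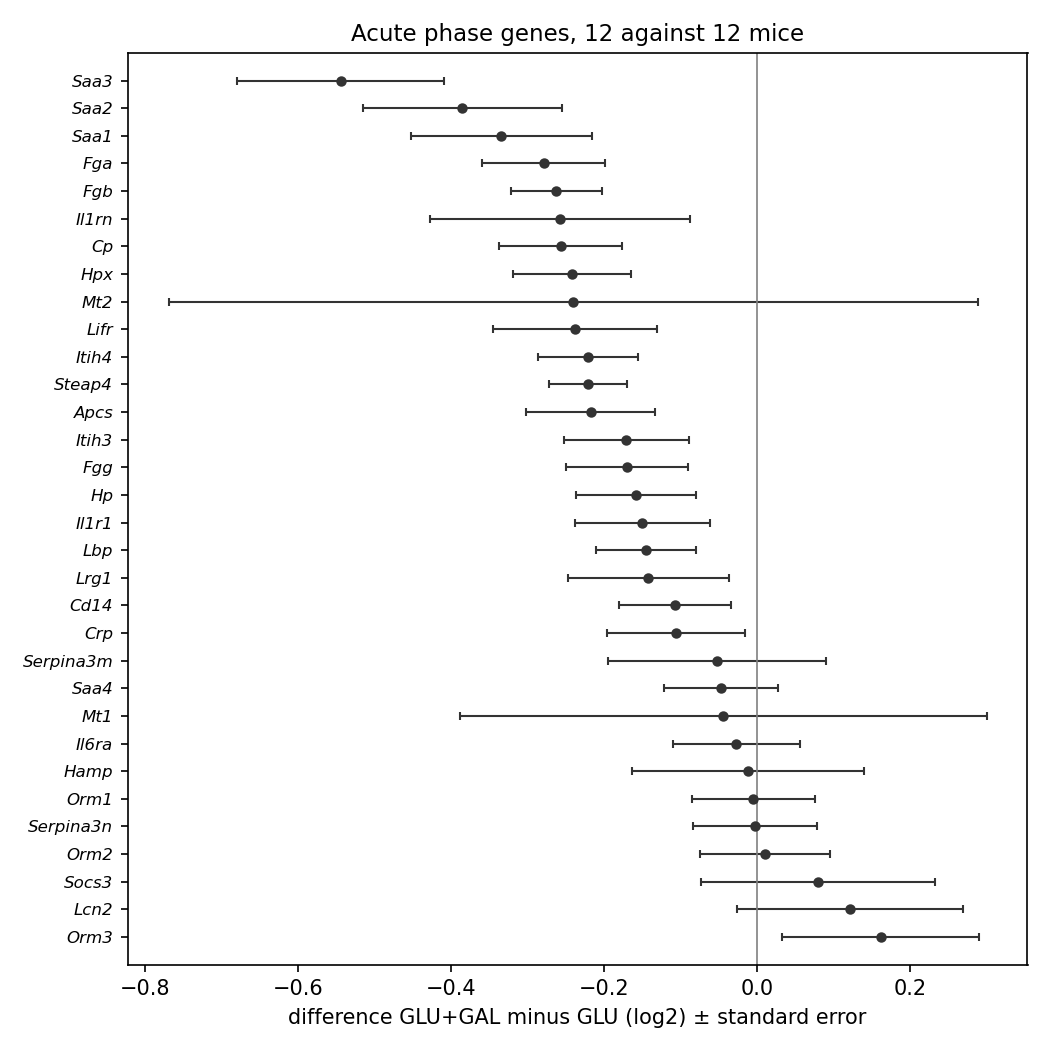
Difference between diets of the 32 measured acute phase genes, ordered by size. The horizontal axis is the log2 difference GLU+GAL minus GLU, points are estimates from 12 mice per diet and bars are standard errors. Saa3, at -0.54, lies farthest below 0, and 28 of the 32 genes lie below 0.

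Genes of the interferon response had lower means in GLU+GAL livers in 28 of 28 measured members, 8 of them at an unadjusted p under 0.05 and 3 when adjusted over the list alone (Igtp, Iigp1 and Cmpk2, the last at -0.34 ± 0.11, SE). The list mean was -0.03 ± 0.26 (SD, n = 12) on GLU and -0.24 ± 0.19 on GLU+GAL, a difference of -0.21. Antigen presentation genes were lower in 14 of 15 members, among them H2-K1 (-0.16 ± 0.06), B2m (-0.13 ± 0.05), Tapbp (-0.16 ± 0.07) and H2-D1 (-0.15 ± 0.06), with a list difference of -0.17. Inflammatory cytokines and chemokines were lower in 14 of 17 members, with a list difference of -0.14, Tnf at -0.33 ± 0.12, Ccl2 at -0.22 ± 0.11 and the adhesion molecule Icam1 at -0.15 ± 0.07. Markers of Kupffer cells, the resident macrophages of the liver, were lower in 16 of 19 members, with a list difference of -0.16, the scavenger receptor Marco at -0.54 ± 0.21, C1qc at -0.23 ± 0.09, Clec4f at -0.22 ± 0.10 and Csf1r at -0.21 ± 0.09, whose other probe gave 0.0017.

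All 4 of these lists passed camera at the preset correlation of 0.01, and none held with an estimated one. The estimated correlation was far above the preset one, at 0.495 for interferon, 0.529 for antigen presentation, 0.210 for cytokines and 0.411 for Kupffer cell markers. The adjusted p with an estimated correlation was 0.290 for the interferon and the cytokine lists, 0.297 for antigen presentation and 0.409 for Kupffer cell markers, and in the permutation test of per-mouse means the adjusted p was 0.393 for each. Array GLU 11 was highest in 3 of them, with list means of 0.55 for interferon response, 0.93 for antigen presentation and 0.52 for Kupffer cell markers. Without it the difference of the antigen presentation list was -0.10 and that of the interferon list -0.16, whose 95% interval then reached 0.0099. With the Kupffer list mean of each mouse as a covariate the interferon difference was -0.09, that of antigen presentation -0.03 and that of cytokines -0.04, each with a 95% interval that included 0 (upper bounds 0.069, 0.098 and 0.039). Within slides 1, 2 and 3 the interferon difference was -0.05, -0.36 and -0.22, that of antigen presentation -0.04, -0.35 and -0.11, that of cytokines -0.14, -0.17 and -0.11, and that of Kupffer cell markers -0.15, -0.15 and -0.17.

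**Figure D2:**
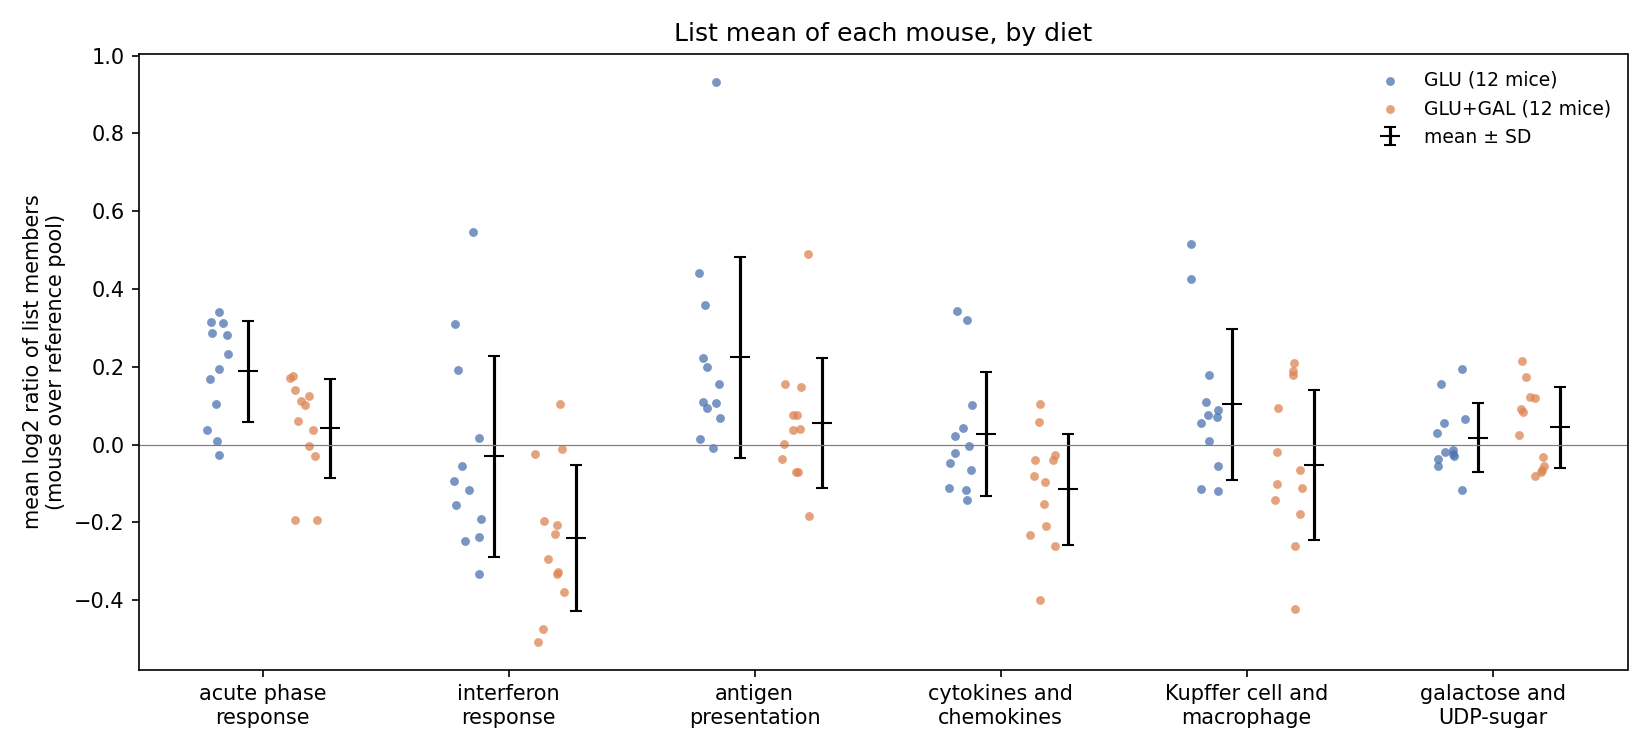
Mean log2 ratio over the members of 6 gene lists in each mouse. The vertical axis is the mean log2 ratio of mouse over reference pool, each point is 1 mouse (12 per diet), and the bars beside the points are means with SD. The acute phase mean was 0.19 on GLU and 0.04 on GLU+GAL, and the highest antigen presentation value, 0.93, belonged to GLU 11.

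A further 8 lists passed camera at the preset correlation and none held with an estimated one, where the lowest adjusted p was 0.282 and the highest 0.755. Growth hormone and IGF axis genes had a list difference of -0.18, with Igfals, the carrier subunit of circulating IGF, at -0.30 ± 0.09 (SE) and past the threshold when adjusted over the list alone, the cytokine signalling inhibitor Socs2 at -0.78 ± 0.37 and the transcription factor Onecut1 at -0.82 ± 0.43. Socs2 and Onecut1 weighed heavily in that mean, the median member being at -0.07, and other probes gave -0.10 for Socs2 and -0.46 for Onecut1. Socs2 differed by -0.09 within slide 2. Array GLU+GAL 4 was lowest in this list (-0.63) and highest in markers of skeletal muscle (0.64) and of kidney and adrenal (0.37), and without it the list difference was -0.15 and the call was lost (adjusted p = 0.0862). Male-predominant liver genes differed by -0.14, with Gstp1 at -0.22 ± 0.08, C9 at -0.22 ± 0.09 and Serpina1e at -0.18 ± 0.08, and the list's call was lost without array GLU 7 (difference -0.06, adjusted p = 0.169). Within slide 1 this list was higher in GLU+GAL, at 0.03. Heat shock genes differed by -0.10, with Hspb1 the 1 member past the threshold adjusted over the list alone, and this call was lost without GLU+GAL 3 (-0.07), 4 (-0.09) or 8 (-0.08). Targets of the fatty acid sensor PPARalpha were lower in 29 of 34 members, with a list difference of -0.08 and Ehhadh, an enzyme of peroxisomal fatty acid oxidation, at -0.18 ± 0.09. The call was lost without GLU 1, 4, 5, 6 or 7 or GLU+GAL 3, 4, 11 or 12, and the difference was -0.01 without GLU+GAL 3. Within slide 1 the PPARalpha list was higher in GLU+GAL, at 0.07. Hepatic stellate cell markers differed by -0.07 (Lrat -0.16 ± 0.09) and markers of T and NK cells by -0.06 (Cd4 -0.19 ± 0.08, and Zap70 in the other direction at 0.25 ± 0.12). The stellate call was lost without GLU 1 or 10 or GLU+GAL 1, 2, 8 or 9 (smallest difference -0.05), and that of T and NK cells without GLU 3, 6, 10 or 11 or GLU+GAL 4, 7, 8 or 9 (smallest -0.03).

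Higher in GLU+GAL were circadian clock genes, by 0.12 over 18 measured members (Usp2 0.35 ± 0.21, SE, and Per2 0.21 ± 0.16, which were 0.22 and 0.10 without GLU+GAL 7), and oxidative phosphorylation genes, by 0.03 with 34 of 40 members higher (Cox7c 0.08 ± 0.05 and Ndufa9 0.07 ± 0.05). Of the clock genes 13 were higher and 5 lower. That list mixes activators and outputs, which ran against each other between mice, so its mean is not a level of the clock. Within slide 2 the clock list was lower, at -0.08, as were Usp2 (-0.05) and Per2 (-0.11). The clock call was lost without GLU 1, 6, 8, 10, 11 or 12 or GLU+GAL 3, 7, 8, 9 or 12 (smallest difference 0.08), and that of oxidative phosphorylation without GLU 10 (0.023) or GLU+GAL 3 (0.024). Over the 19 settings other than leaving out 1 array, the oxidative phosphorylation difference ran from 0.00065 to 0.12 and the call was lost in 4. With an estimated correlation the adjusted p was 0.282 for growth hormone and IGF axis, 0.605 for male-predominant and for clock genes, 0.622 for heat shock, 0.755 for PPARalpha targets, 0.523 for stellate cells, 0.643 for T and NK cells and 0.700 for oxidative phosphorylation. In all, 13 of 45 lists passed camera at the preset correlation, 11 lower and 2 higher. The same number, 13, passed without GLU+GAL 12, and 10 passed without GLU+GAL 4. No list mean differed between the diets in the permutation test over mice after adjustment, where 4 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.393.

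Named genes of the Leloir pathway, which converts galactose to glucose 1-phosphate, did not differ detectably between the diets. Galk1, galactokinase, differed by a log2 of 0.0013 ± 0.07 (SE) and Galt, galactose-1-phosphate uridylyltransferase, by 0.03 ± 0.06, with signs that varied between slides. Galm, which turns galactose between its ring forms, differed by -0.01 ± 0.06 and Galk2 by 0.02 ± 0.05. Ugp2, which makes UDP-glucose, had the largest difference of the 7 named genes at 0.11 ± 0.08 (unadjusted limma p = 0.168). The phosphoglucomutases Pgm1 and Pgm2, whose symbols in the array files are exchanged relative to current names, differed by -0.04 ± 0.06 and 0.0024 ± 0.08. For Galm a second probe had the opposite sign. The whole list of 12 genes had a mean of 0.02 ± 0.09 (SD, n = 12) on GLU and 0.04 ± 0.10 on GLU+GAL, with a camera adjusted p of 0.482.

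Of the lists for sugar and lipid metabolism, that of PPARalpha targets and fatty acid oxidation passed camera at the preset correlation and not with an estimated one (adjusted p = 0.755), and the others did not pass. Fatty acid synthesis genes were lower in 16 of 18 members with a list difference of -0.10 against an SD between mice of 0.43 on GLU and 0.34 on GLU+GAL (camera adjusted p = 0.0573), and glycolysis genes with the targets of the carbohydrate sensor ChREBP differed by -0.08 (0.131). Gluconeogenesis differed by 0.06 (adjusted p = 0.181), glycogen metabolism by 0.03 (0.711), cholesterol synthesis by 0.01 (0.999), bile acid synthesis and transport by -0.02 (0.377), and genes of fibrosis and extracellular matrix by 0.02 (0.514). Markers of endothelial cells (0.01), cholangiocytes (0.05), B cells (-0.06), neutrophils (-0.07), erythroid cells (0.01), adipocytes (0.11), pancreas (-0.01), kidney and adrenal (0.04) and skeletal muscle (0.04) did not pass either. The other lists that did not pass were triglyceride synthesis (-0.01), ketone bodies (-0.07), tricarboxylic acid cycle (0.02), urea cycle and amino acid breakdown (0.01), insulin signalling (-0.01), glucocorticoid-responsive genes (0.04), immediate early genes (-0.08), unfolded protein response (0.05), NRF2 targets (-0.03), CAR and PXR targets (0.05), p53 targets (-0.06), cell cycle (-0.03), female-predominant genes (0.08), and pericentral (0.04) and periportal (-0.01) hepatocyte genes. Camera placed the cholesterol, glucocorticoid, erythroid and CAR and PXR lists lower although the differences of their means were above 0. Adjusted over the list alone, 1 gene each was lower in the bile acid, immediate early and neutrophil lists, named after their values were seen: Cyp2c70, a bile acid hydroxylase (-0.31 ± 0.08, SE), the AP-1 factor Jund (-0.31 ± 0.09) and Ly6g (-0.23 ± 0.06).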

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

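The tests in this part were chosen after the values were seen. Y-linked genes were outside the comparisons because their probes were below background on nearly all arrays, yet array GLU+GAL 12 gave a signal for Eif2s3y 6.26 times that of the other 23 arrays (Cy5 relative to the array's median), above all 12 GLU arrays. The probe was not well above background on those 23, so the ratio is over background and is no fold of expression. A stray signal on a single spot is argued against by the count of Y-linked genes, since 2 genes, Eif2s3y and Ddx3y, were well above background there on 3 probes and on none of the other arrays. The rest of the 7 Y-linked probes, all those of Uty and another of Ddx3y, stayed at background on this array. Their signals were 0.974 to 1.155 times those of the other 23. Female RNA mixed with some male RNA is argued against by Xist, whose level of -2.57 (log2 over the array's median) lay below the lowest other array, at -1.91, by more than their SD of 0.29. A liver with the usual adult male expression pattern was tested by the mean of female-predominant minus male-predominant liver genes, which was -0.057 on this array, above 10 of the other 23 arrays and just below their median of -0.0066. The bound set for that score was their median, so the test did not decide, and a male mouse or a wrong sample, with or without an adult male liver pattern, stays open. The design names no group of this kind, and no biological explanation other than that score was tested.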

How the results depend on the processing

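Leaving out sets of arrays with a bright reference or Y-linked signal was chosen after the data were seen. The count of genes past the threshold was 0 under the other settings run, except that 1 gene (Zfp787) passed without GLU 3, so leave-one-out counts ran from 0 to 1, and 179 genes had an unadjusted p under 0.01 against 186.5 expected by chance. Lists past camera numbered 13, from 9 to 16 with 1 array left out, 6 within slide 1 and 26 within slide 3, 1 with an estimated correlation and 1 with fry. For slides alone and for the set tests the cause was not tested. No per-mouse list mean passed under any setting (leave-one-out 0 to 0), and the random slide block was not run for it. Aquantile leaves log ratios as they are, so it tested nothing, and scan date coincided with slide and was not run. Without the 3 arrays with the brightest reference 11 lists and 0 genes passed, and without GLU+GAL 12 as well, 10 and 0. With the replicate number as a block 0 genes, 13 lists and 0 list means passed; 8 of 12 same-numbered pairs correlated above 0.1 (range -0.38 to 0.52, mean 0.15 against -0.013 for different numbers) and 2 GLU arrays correlated best with their own number. These values do not exclude a factor shared by same-numbered samples, and 6 of the 12 pairs lay on 1 slide, so slide may add to the correlation. The number was not a block in the main fit, and what the numbers mark is not given in the sources used here.

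Direction turned for the genes and lists below, and of these the acute phase list alone passed under the setting that turned it. Within slide 1 these were Pgm2 -0.030, Galk1 -0.11, Galk2 -0.093, H2-K1 0.061, Ahsa1 0.012, the PPARalpha list 0.071 and the male-predominant list 0.026. Within slide 2 they were Ugp2 -0.056, Galm 0.063, Usp2 -0.050, Cry2 -0.22, Per2 -0.11, Uqcrb -0.0063 and the circadian list -0.082. Within slide 3 they were Pgm1 0.10, Galt -0.089, Pgm2 -0.046, Galk1 -0.071, Galk2 -0.00074, Galm 0.064, Acads 0.00099 and the acute phase list 0.0019. Other turns were Galm with Agilent's processed signals (0.0018), Pgm1 (0.021) and Pgm2 (-0.045) with median centring, Pgm2 (-0.028), Galk1 (-0.025) and Galm (0.038) with Cy5 alone, Pgm1 (0.033) and Galm (0.011) in the authors' value table, Galm (0.020) and Acta2 (0.0043) with probes averaged, Galk1 with array weights (-0.029), Galk1 without the brightest arrays (-0.015), and Galk1 (-0.0049) without GLU+GAL 12 as well. With 1 array left out, Pgm2 ran from -0.031 to 0.032, Galk1 from -0.033 to 0.035, Galk2 from -0.0027 to 0.038 and Galm from -0.053 to 0.010. The cause of these turns was not tested. Apart from leaving out 1 array, 1443 of 1474 values of named genes and 198 of 266 of lists held their direction and side of the threshold, and 64 list calls were lost. Much of this was fixed in advance, so the counts do not measure robustness. Genes named for the largest differences were chosen for 1 direction on all 3 slides. Slide and replicate blocks hold the diets equally and so leave a difference almost as it is. In the main limma fit no gene was near the threshold (lowest adjusted p 0.672). The acute phase, interferon, antigen presentation, cytokine and Kupffer lists kept their camera call with each array left out, while the circadian list lost it in 11 of 24 cases, PPARalpha in 9, T and NK cells in 8 and stellate cells in 6. Spots not well above background were many, and genes below it were not compared.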

Other observations

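The lists of complement genes and of interferon-inducible GTPases below, their adjustment for Kupffer markers, the leave-one-out tests of the acute phase and interferon lists and the tests of spread were chosen after the values were seen; the other tests were set before their result. Complement components and their inhibitors, plasma proteins of innate defence made mostly by hepatocytes, were lower in GLU+GAL livers in 25 of 27 measured genes, 15 of them at an unadjusted p under 0.05 and none higher. Cfb differed by -0.21 ± 0.05 (SE), Cfi by -0.20 ± 0.05, the C1 inhibitor Serping1 by -0.18 ± 0.05, Hc (complement C5) by -0.23 ± 0.07 and C3 by -0.24 ± 0.08, while Masp1 was at 0.01 ± 0.07 and Cfd, the complement factor D also made by adipocytes, at 0.44 ± 0.38. The mean per mouse was 0.07 ± 0.10 (SD, n = 12) on GLU and -0.07 ± 0.10 on GLU+GAL, and 11 of 12 GLU+GAL mice lay below the GLU mean (permutation p = 0.00351, adjusted over these 2 lists 0.00702). The difference of -0.14 was -0.05, -0.22 and -0.14 within slides 1, 2 and 3, and 6 of the genes are also in the fixed lists. Of these, 3 are C1q chains, made by macrophages and shared with the Kupffer list (C1qc -0.23 ± 0.09, C1qa -0.20 ± 0.10 and C1qb -0.19 ± 0.12). With the Kupffer list mean as a covariate the difference was -0.11 (95% interval -0.20 to -0.02), and without these 3 genes -0.12 (-0.22 to -0.02).

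The interferon-inducible GTPases of the IRG and GBP families, which act against intracellular microbes, were lower in 18 of 19 genes, with Tgtp2 at -0.58 ± 0.22 (SE), Gbp6 at -0.45 ± 0.17 and Gbp5 at 0.07 ± 0.15. Their mean differed by -0.31 (permutation p = 0.00711, adjusted 0.00711), with an SD of 0.36 on GLU and 0.20 on GLU+GAL, and within slides 1, 2 and 3 by -0.09, -0.55 and -0.28. With the Kupffer list mean as a covariate the difference was -0.14 (95% interval -0.33 to 0.05). Of these genes 5 are in the fixed lists. Both lists were picked because some members stood out, so their p-values are too small.

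Chance cannot be excluded as the source of the counts over all genes and lists. The 24 arrays were split into 12 and 12 in 100 ways, the real one among them. Of these splits, 27 gave at least the real 179 genes at an unadjusted p under 0.01 (other splits: median 117, highest 779). At least 13 lists passed camera at the preset correlation in 36 (other splits: median 11, highest 22). The splits ignored slide, whereas the real one held 4 arrays per diet on each slide. An additive slide effect cancels in the real difference but not in unbalanced splits, so these counts are no exact chance rate. The split with 779 genes, several times the real count, may reflect a structure among the samples, such as slide, or the correlation between genes, which was not tested. With an estimated correlation, 3 of the 99 other splits and the real one gave 1 list.

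The lower acute phase list was weighed against 3 explanations. A shift of the Cy3 reference between diets is argued against, since in Cy3 alone the list differed by -0.00050 (95% interval -0.03 to 0.03), although Cy5 alone gave -0.095 and median centring in place of loess -0.10, so part of the -0.15 depends on the normalisation. Lower Kupffer marker RNA is argued against as the whole cause for this list (not for the interferon, antigen presentation and cytokine lists, which shrank to -0.09, -0.03 and -0.04), since with the Kupffer list mean of each mouse as a covariate the difference was -0.14 (-0.26 to -0.02). The marker mean only stands in for cell number, which was not measured, so fewer Kupffer cells or macrophages in GLU+GAL livers are not excluded. A single mouse is argued against too, the smallest difference with 1 mouse left out being -0.12 (without GLU+GAL 1), with each of the 24 intervals below 0; for the interferon list the same test did not decide, the smallest difference being -0.16 without GLU 11, with an interval that reached 0.0099. An effect of diet is consistent with these values, as a hypothesis, but chance over the lists, the adjusted p of 0.393 over mice and a list mean near 0 on slide 3 keep it open.

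Clock genes varied more between GLU+GAL mice, with an SD of the list mean of 0.25 against 0.10 on GLU, a ratio of 2.60. Chance among the 45 lists fits this ratio (permutation p = 0.0173, adjusted 0.259). Mice at different clock phases may underlie the variation: the mean of the activators Arntl and Clock correlated with that of 8 output and repressor genes (such as Dbp, Tef and Per3) at Pearson r = -0.90 over the 12 GLU+GAL mice (permutation p = 0.00013, Spearman rho = -0.85, p = 0.0008) and at -0.65 over the 12 GLU mice (p = 0.0198, rho = -0.72, p = 0.0105). Adjusted over the 2 diets, the Pearson p-values were 0.00026 and 0.0198 and the Spearman ones 0.0016 and 0.0105. Without the 2 mice farthest from the median activator level r was -0.77 and -0.75, and within slides 1, 2 and 3, over both diets after removing diet means, -0.87, -0.83 and -0.89. As the correlation was negative on both diets, it cannot tell why the spread was wider on GLU+GAL. The hour at which each mouse was killed was not analysed here. Whether the mice differed in phase, and whether through collection or diet, stays untested.

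Neutrophil and bone marrow markers had an SD between mice of 0.29 on GLU+GAL and 0.10 on GLU (ratio 2.96, permutation p = 0.00027, adjusted over 45 lists 0.0122), from -0.42 in GLU+GAL 1 to 0.57 in GLU+GAL 11. That array was also the highest in adipocyte markers (0.65) and in fibrosis and matrix genes (0.33), and without it the ratio was 2.30. The mean of female-predominant minus male-predominant liver genes ran from -1.88 in GLU 7 to 0.61 in GLU+GAL 11.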
